A study of Homo sapiens with 12 samples.

How the data were processed

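Poly(A) RNA from 12 samples of HK-2, an established line of human renal proximal tubular epithelial cells, was sequenced, per the labels' protocols. The labels divide the 12 samples into 6 in which cells lacking endogenous nucleophosmin (NPM1) had received wild-type NPM1 and 6 in which they had received NPM1 with the K257R substitution. The submitters' processing notes name the genome build GRCh38, cutadapt 1.9 and FastQC. The aligner, the counting tool and the annotation release are not given in the sources used here.

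A single table of 28026 gene rows was examined. It pairs each gene's position and transcripts with 12 columns that the file header names as FPKM and 12 that it names as count, made by the authors. These 24 columns carry 12 library names that consist of a letter, B or C, and a replicate number. The sample labels use neither letter, and no label says which letter stands for wild-type NPM1 and which for K257R. Assigning the letters by column order or by expression level would have fixed the direction of every fold change by assumption. The letters also leave open whether the columns hold the samples described by the labels. The 24 columns were therefore given to no sample or group and were not analysed here, not even as B against C without a direction. Library depths, expression values and differences are not reported.

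The comparison planned before the data were examined was K257R against wild-type NPM1, 6 libraries against 6. It was to use limma on log-transformed FPKM, or a negative binomial quasi-likelihood test instead if the table held raw counts. Tests of gene lists were also planned, for those of 34 lists with enough tested members. None of these tests was run. The lists hold 1000 different gene symbols, of which 881 (88.1%) matched a gene name of the table exactly. The match was poor for some lists: 6 of 22 antigen presentation genes and 0 of 13 mitochondrially encoded genes matched, and 0 of the rows used here lay on the mitochondrial genome. The rule for naming genes by their test results was not applied. NPM1 was to be named whatever its result, and only its position is given.

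Positions were taken from the table. Those of NPM1 alone were compared with RefSeq for the same assembly and with GENCODE release 29, which is also on GRCh38. The codon of K257 was located by translating the coding sequence of each NPM1 transcript of GENCODE release 29 and mapping it to the genome through the annotated exons, with Python 3.11.15 and pandas 2.3.3. All positions are given as a genome browser shows them. A gene row was called wide if its start and end lay more than 3 Mb apart.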

Results

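The study addressed the effect of lactylation of NPM1 at K257, a lysine near its C terminus, on the transcriptome of HK-2 cells. NPM1 is an abundant nucleolar phosphoprotein that takes part in ribosome assembly and histone chaperoning. Lactylation is the attachment of a lactyl group to a lysine side chain, and a K257R protein carries an arginine in place of the lysine, so that this position cannot be modified in that way. NPM1 had been knocked out, and the cells were reconstituted with wild-type NPM1 in 6 samples and with NPM1 K257R in 6 samples. The design implies a single comparison, K257R against wild type, with 6 libraries in each group. Such a comparison cannot separate the loss of lactylation from other effects of the substitution.

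This comparison was not made. The deposited table names its 12 libraries by the letters B and C, and the labels do not say which letter belongs to which form of NPM1. No label ties a column of the table to any of the 12 samples, and columns without such a tie were left out of every step. No expression level, fold change, test result or total count is therefore given. Differences between the libraries lettered B and those lettered C, whose size would not depend on which letter is which, were not examined either.

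The endogenous NPM1 gene could be placed in the genome from the annotation. The positions below are those of that reference locus and not of the NPM1 copy introduced into the cells. In the deposited table, NPM1 (gene identifier 4869) lay on the plus strand of chromosome 5 from 171387116 to 171410900, a span of 23785 bp on GRCh38, and was paired with 7 transcripts. RefSeq gave the same start and end. GENCODE release 29 gave the same start and placed the end at 171411137, for a span of 24022 bp.

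In the transcript NPM1-201, which encodes 294 residues, the lysine K257 was encoded by the codon AAA at positions 171405401 to 171405403 of chromosome 5. The codon formed the last 3 bases of exon 9 of 11, whose coding part runs from 171405302 to 171405403. It thus lay in coding sequence, outside both untranslated regions, directly before a splice junction of the endogenous gene.

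GENCODE release 29 lists 6 NPM1 transcripts with a coding sequence, and 4 of them contain this codon. The codon encoded K257 in NPM1-201 and NPM1-204, both of 294 residues, and in NPM1-203, a form of 259 residues. In NPM1-202, a form of 265 residues, the same lysine was residue 228. NPM1-202 and NPM1-203 each have 10 coding exons, against 11 in NPM1-201 and NPM1-204. The coding sequences annotated for the 2 remaining transcripts, NPM1-208 and NPM1-211, encode 111 and 59 residues and do not contain the codon. Whether these coding sequences are complete was not checked, so they are not shown to be full NPM1 forms that lack the lysine. The labels do not say which isoform was used for reconstitution.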

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

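No paired analysis was possible because no library column was used: the columns match no sample's labels, although their names carry replicate numbers. The filter on low values, the tests and their alternatives laid down before the data were examined were not run, because no library column was used. Other normalizations and fits with libraries left out were not run either, and what depth limits was not assessed. The number of wide gene rows was 1495 at a limit of 3 Mb, 1525 at 2 Mb and 1472 at 5 Mb. None of these limits, 3 Mb included, was laid down before the data were examined.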

Other observations

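Of the 28026 gene rows, 26116 named a nuclear chromosome as their sequence and 1910 (6.82%) named another sequence. The start and end of 1495 rows were more than 3 Mb apart, and 1491 of these rows named such another sequence. The remaining 4 wide rows named a chromosome. Whether both positions of a wide row lie on the sequence it names was not checked. The 1910 rows are therefore not a count of genes located on other sequences. The positions of the wide rows were not compared with another annotation.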
